A study of Mus musculus with 10 samples.

How the data were processed

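RNA was measured in oesophageal tissue of 10 mice given 4-NQO (4-nitroquinoline 1-oxide, a DNA-damaging carcinogen used to induce squamous tumours of the upper digestive tract). The labels put 5 mice in a Grhl3 knockout group (Grhl3 KO) and 5 in a wild-type group, and each library is named here by its group and the sample number in its title. Per the labels' protocols, RNA was extracted with a column kit for small samples and libraries were made with a strand-preserving poly(A) kit. All mice are labelled C57BL/6.

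The deposited table holds whole-number counts per gene for 22740 protein-coding genes, without normalization, in 10 columns that were joined to the sample titles by sample number. The wild-type columns name the group as the titles do, and the Grhl3 KO columns carry "L2Cre" in its place; what this stands for is not given in the sources used here. Per the submitters' processing notes, reads were counted with featureCounts (version not given there) against GRCm38; the aligner and the annotation release are not given in the sources used here. The deposited file is named as reverse-stranded counts and its biotype column holds only protein-coding genes. Non-coding genes and pseudogenes were therefore not analysed here. How reads that match several genes were treated is not given in the sources used here, so genes with near-identical copies carry uncertain counts. The table holds 0 other columns of per-sample values and 0 rows that name no gene. Gene positions come from the GENCODE annotation of GRCm38, in which 21842 of the 22740 identifiers were found.

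Total counts ran from 15.3 to 32.9 M per library. Genes were kept with the filterByExpr function of edgeR 4.0.16 in R 4.3.3, with its minimum count of 10 and minimum total count of 15, which left 13731 genes; 4661 genes were at 0 in every library. Counts were scaled by TMM factors, and each gene was tested with edgeR's quasi-likelihood F-test with robust dispersion estimates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are Grhl3 KO minus wild type, and their standard errors (SE) follow from the F statistic. CPM stands for counts per M of TMM-scaled library size, with M the SI prefix mega. Log2 CPM values carry a prior count of 2. The 95% limits of a fold change use the moderated degrees of freedom. Single measures per library were compared by exact two-sided permutation tests over all assignments of 5 and 5 libraries, whose smallest possible p is 0.00794.

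Before the data were examined, 42 gene lists were fixed: the grainyhead-like family, genes reported elsewhere as GRHL3 targets, epithelial programmes, signalling and stress processes, RNA quality classes, markers of other cell types and a Y-linked list used as a sex check. The other 41 lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, for lists with at least 3 measured members, with Benjamini-Hochberg adjustment over the lists. The same lists were tested with a correlation estimated from the data and with fry. The genes named in the text follow a rule fixed at the same time. It takes the grainyhead-like family and the reported targets. It takes up to 12 genes per direction with an adjusted p under 0.05, no overlap between the groups, a mean of at least 1 CPM and no predicted-model name, or the 5 genes of smallest p in a direction where fewer than 5 qualify. In these data 4 genes qualified among those higher and 3 among those lower, so the 5 of smallest p were named in each direction. It also takes up to 4 members of smallest p per list and the 2 most abundant members of each cell type list. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

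The alternatives tried were 3 other scalings, DESeq2 1.42.0, limma voom with and without quality weights, dispersion estimates that were not robust, no filter and a filter of 1 CPM in 5 libraries, leaving out each library, covariates for Y-linked, skeletal muscle, immune and epithelial content, 1 surrogate variable (sva 3.50.0), the number series of the samples as a batch, and removal of the skeletal muscle genes. A further 3 alternatives that leave out wild-type libraries were added after the data were seen. The number series was treated as a possible batch because the wild-type libraries 1528, 1555 and 1561 carry sample numbers far from those of the other 7 libraries; the labels do not say what the numbers mean. Similarity to other genes was measured with blastn 2.17.0 on annotated transcripts, counting stretches of at least 75 bases with at least 95% identity.

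The tests were tried on simulated data in which 200 of the 13731 genes were changed between Grhl3 KO and wild type. edgeR recovered 62% of genes changed 2-fold and 91% of genes changed 4-fold, with 7 false calls. DESeq2 recovered 79% and 97% with 35 false calls, and limma voom 61% and 90% with 7 false calls. The simulation drew each gene independently, without a sex or number series difference, and changed only genes with a mean of at least 1 CPM. These rates may therefore not hold in the real data. The biological coefficient of variation in the real data was 27.9%. The p-values measure the spread between the 10 libraries, which the series describes as separate mice.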

Results

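The series profiled gene expression in the oesophagus of mice exposed to 4-NQO, to ask how loss of Grhl3, a grainyhead-like transcription factor of surface epithelia, changes the tissue. Libraries came from 5 Grhl3 KO mice and 5 wild-type mice. The sample labels describe the Grhl3 KO tissue as oesophageal tumour and the wild-type tissue only as oesophageal tissue, while the series' own design text speaks of tumours from both genotypes. Genotype and tissue label therefore differ between the same libraries. Total counts ran from 15.3 to 32.9 M per library and averaged 24.8 ± 8.21 M in Grhl3 KO and 19.9 ± 2.17 M in wild type (SD, n = 5 each; exact two-sided permutation p = 0.246). The first principal component held 24.6% of the variance and did not separate the groups (exact two-sided permutation p = 0.230). Pairs of libraries of the same group had a mean correlation of 0.963 across genes and pairs from different groups 0.960.

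All 5 Grhl3 KO libraries held counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Wild-type libraries 1528 and 1555 held almost none, with Eif2s3y at 0 and 0.0539 CPM against 68.4 to 75.6 CPM in the 5 Grhl3 KO libraries and wild-type libraries 1028 and 1048. Wild-type library 1561 lay between, with Eif2s3y at 24.9 CPM. The X-linked gene Kdm5c stood at 176 and 165 CPM in libraries 1528 and 1555, against 97.1 to 136 CPM in the other libraries. Kdm6a stood at 57.7 and 55.0 against 35.2 to 44.4 CPM, and Eif2s3x at 42.45 and 44.25 against 24.75 to 36.73 CPM. These genes escape X inactivation, so their levels go with female mice and argue against loss of the Y chromosome alone. Ddx3x, another such gene, did not set the libraries apart, and the labels give no sex. The wild-type group thus mixes libraries with and without Y-linked expression, and the Grhl3 KO group does not.

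Grhl3 itself was not lower in the libraries labelled Grhl3 KO. The gene (ENSMUSG00000037188, chromosome 4, 135541888 to 135573630, GRCm38) was at 222 ± 66.8 CPM in Grhl3 KO and 207 ± 112 CPM in wild type (SD, n = 5 each). Its log2 fold change was 0.11 (SE 0.35, 95% limits −0.66 to 0.87), with an adjusted p of 0.979 in edgeR's quasi-likelihood test. The 5 Grhl3 KO libraries 1026, 1027, 1035, 1036 and 1043 stood at 135, 234, 191, 235 and 317 CPM. The 5 wild-type libraries 1028, 1048, 1528, 1555 and 1561 stood at 363, 114, 164, 283 and 109 CPM. The columns of the Grhl3 KO libraries contain the word Cre, a recombinase used to delete genes, and the series title speaks of conditional knockouts, in which only cells with active Cre lose the gene. The table sums reads over the whole gene, so it does not show whether a part of the transcript is missing. The counts thus neither bear out nor contradict the genotype labels, and "Grhl3 KO" below means the libraries so labelled. The other family members missed the threshold: Grhl1 was at 214 ± 60.9 against 141 ± 51.4 CPM (log2 fold change 0.60, 95% limits 0.02 to 1.18, edgeR adjusted p = 0.692) and Grhl2 at 85.3 ± 6.50 against 92.9 ± 8.56 CPM (−0.12, edgeR adjusted p = 0.824).

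**Figure D1:**
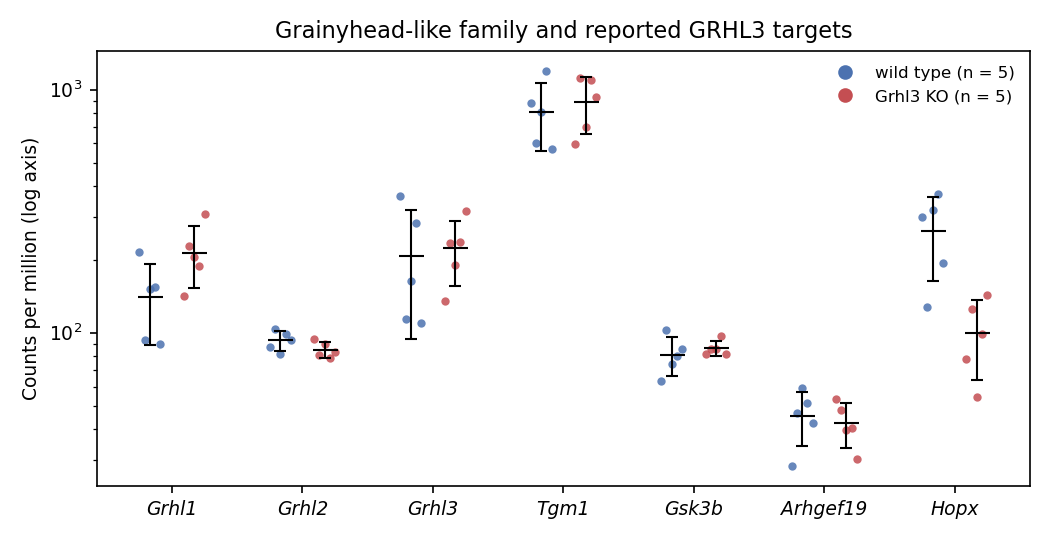
CPM on a log axis for the grainyhead-like family and 4 reported GRHL3 targets in each library, with the mean ± SD of 5 wild-type (blue) and 5 Grhl3 KO (red) libraries. Grhl3 overlaps between the groups, at 222 CPM in Grhl3 KO and 207 CPM in wild type, and Hopx has the widest gap between group means, at 100 against 262 CPM.

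The 9 genes reported elsewhere as GRHL3 targets showed no common shift, with 5 higher and 4 lower (camera adjusted p = 0.676; test and mean negative, median 0.07). Hopx, which encodes a small homeodomain protein of differentiating epithelium, was at 100 ± 35.8 CPM in Grhl3 KO and 262 ± 99.5 CPM in wild type, a log2 fold change of −1.39 (SE 0.32). It missed the threshold over all genes (edgeR adjusted p = 0.257) and was the 1 member that passed when adjusted over the list alone. The protease gene Klk5 had a log2 fold change of −1.25 (edgeR adjusted p = 0.651), and the lipid transporter gene Abca12 one of 0.38 (edgeR adjusted p = 0.815). Tgm1, encoding the transglutaminase that crosslinks the cornified envelope, differed by 0.13 and its relative Tgm5 by −0.02. Gsk3b differed by 0.09, Alox12b by 0.10 and Arhgef19 by −0.11, none of them past the threshold.

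Against this background, 11 genes passed an adjusted p of 0.05 between Grhl3 KO and wild type, 4 higher and 7 lower. Krt1, a keratin of cornifying epidermis, rose 8.27-fold, from 24.2 ± 11.2 to 200.3 ± 97.7 CPM (SD, n = 5 each). Edn1, encoding the vasoactive peptide endothelin, rose 3.10-fold and Msln, encoding the surface glycoprotein mesothelin, rose 3.90-fold. Hmgn2, encoding a nucleosome-binding protein, fell 8.36-fold, from 15.4 ± 4.88 to 1.83 ± 0.412 CPM, and Sptlc3, encoding a subunit of the enzyme that starts sphingolipid synthesis, fell 13.9-fold, from 26.0 ± 13.3 to 1.90 ± 0.947 CPM. For each of the 11 genes every Grhl3 KO library lay on one side of every wild-type library. Over all 13731 genes tested, 186 separated the groups in this way, where chance gives 0.794% or 109 genes on average. This number was not counted in other divisions of the libraries.

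In edgeR's quasi-likelihood test, Krt1 (ENSMUSG00000046834, chromosome 15, 101845426 to 101850794) had a log2 fold change of 3.05 (SE 0.43, adjusted p = 0.0358). Msln had 1.97 (SE 0.28, edgeR adjusted p = 0.0358), Edn1 1.63 (SE 0.22, edgeR adjusted p = 0.0318) and Agpat4, encoding an acyltransferase of phospholipid synthesis, 1.38 (SE 0.18, edgeR adjusted p = 0.0318). Rhpn2, the next higher gene by p, missed the threshold at 2.05 (edgeR adjusted p = 0.0569). Hmgn2 (ENSMUSG00000003038, chromosome 4, 133964738 to 133968650) had −3.06 (SE 0.25, edgeR adjusted p = 0.00135) and Sptlc3 (ENSMUSG00000039092, chromosome 2, 139493913 to 139637674) −3.80 (SE 0.46, edgeR adjusted p = 0.0318). Dnase1l3, encoding a secreted DNase, had −2.19 (SE 0.28, edgeR adjusted p = 0.0318). The predicted genes C130079G13Rik and Gm9696, whose midpoints lie 31.4 kb apart on chromosome 3, had −3.08 and −2.13 (edgeR adjusted p = 0.0318 and 0.0382). The remaining called genes, 1700055N04Rik at −3.37 and 6430571L13Rik at −2.16 (edgeR adjusted p = 0.0397 for each), were named after their values were seen.

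Hmgn2 was the 1 gene past the threshold in every alternative tried (edgeR, DESeq2 or limma adjusted p from 1.73e-27 to 0.0382). With 1 library left out at a time, Krt1 and Msln kept their calls only without Grhl3 KO library 1026, Agpat4 in 3 of 10 cases, and Sptlc3, Dnase1l3 and Edn1 in 4 each; the Krt1 fold change ran from 2.84 to 3.28 on the log2 scale. Within the number series of the Grhl3 KO mice, which holds 5 Grhl3 KO and 2 wild-type libraries, the Hmgn2 log2 fold change was −3.27 and Hmgn2 alone passed. The Krt1 log2 fold change there was 2.87, the Sptlc3 log2 fold change −3.74, the Msln log2 fold change 2.04, the Edn1 log2 fold change 1.37, the Agpat4 log2 fold change 1.29 and the Dnase1l3 log2 fold change −1.79. Over all alternatives the adjusted p of these 6 genes reached 0.526, 0.282, 0.475, 0.439, 0.484 and 0.406. The other number series holds 3 wild-type libraries and no Grhl3 KO library. Of the longest annotated Hmgn2 transcript, 92.3% lies in stretches at least 95% identical to transcripts of 12 other genes, 11 of them pseudogenes, so its count is uncertain. The same share was 0.0% for Krt1, Sptlc3, Dnase1l3, Edn1 and Msln, and 29.8% for C130079G13Rik, whose count is uncertain for the same reason.

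**Figure D2:**
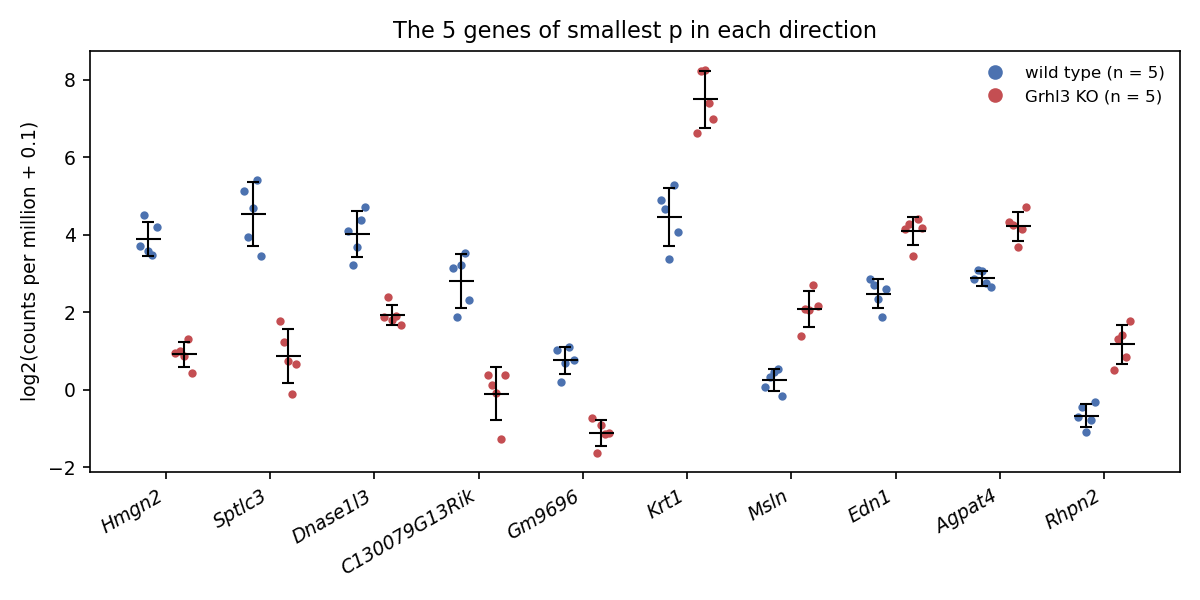
Log2 of CPM plus 0.1 in each library for the 5 genes of smallest p in each direction, with the mean ± SD of the log2 values of 5 wild-type (blue) and 5 Grhl3 KO (red) libraries. The groups do not overlap in any of the 10 genes; Rhpn2 missed the threshold at an adjusted p of 0.0569.

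Genes close to Grhl3 on chromosome 4 appeared repeatedly among the smallest p-values. Besides Hmgn2, whose midpoint lies 1.59 Mb from that of Grhl3, Stpg1 (41.5 kb away) and the microtubule regulator gene Stmn1 (1.09 Mb away) had log2 fold changes of 3.42 and −1.31, each at an edgeR adjusted p of 0.0834; of the Stmn1 transcript, 42.5% is near-identical to 1 pseudogene. These genes were singled out after their values were seen. Within 5 Mb on either side, 19 of 138 tested genes (13.8%) had an unadjusted p under 0.05, against 7.14% of all genes with a position. Of these, 5 genes had a p under 0.001, among them Cnksr1 at 0.64 on the log2 scale and the 3 already named.

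**Figure D3:**
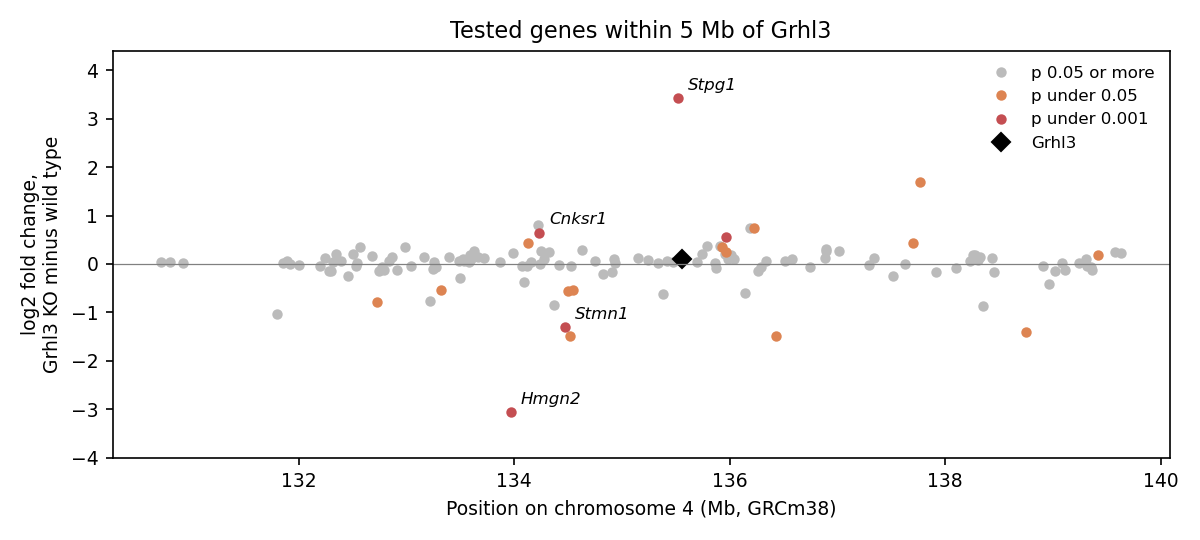
Log2 fold change, Grhl3 KO minus wild type, against the position in Mb on chromosome 4 (GRCm38) of each tested gene within 5 Mb of Grhl3, coloured by unadjusted p; the diamond marks Grhl3. The 5 genes with p under 0.001 include Hmgn2 at −3.06 and Stpg1 at 3.42, both at lower positions than Grhl3, which was at 0.11.

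Among the epithelial lists, squamous differentiation and the cornified envelope did not move as a group. Of 49 measured members 23 were higher and 26 lower (camera adjusted p = 0.957; mean −0.09 and median −0.06 with a test direction upward). Krt1 was the 1 member that rose over all genes; adjusted over the list alone, Krt1 rose and Hrnr, encoding the cornified envelope protein hornerin, fell. Hrnr was at 2.36 ± 1.38 CPM in Grhl3 KO and 41.5 ± 58.5 CPM in wild type (edgeR adjusted p = 0.206 over all genes). Wild-type library 1528 stood at 145 CPM and the other 4 wild-type libraries at 6.74 to 25.5 CPM; without it the Hrnr log2 fold change was −2.76 in place of −4.19. Suprabasin (Sbsn) had a log2 fold change of −1.06 and the envelope precursor Sprr2f one of 1.36 (edgeR adjusted p = 0.426 and 0.451). The list passed downward without wild-type library 1048 (mean −0.24) and upward without wild-type libraries 1028 and 1528 (mean 0.38), with adjusted p from 7.06e-05 to 0.996 over all alternatives.

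Basal keratinocyte genes were lower as a group in camera with a preset correlation, with 17 of 20 members lower and a mean log2 fold change of −0.37 (camera adjusted p = 0.000763). The adjusted p was 0.99 with an estimated correlation, and the call ended without Grhl3 KO library 1043 (mean −0.26). No member passed over all genes or adjusted over the list alone: the neurotrophin receptor gene Ngfr was at −0.64, Pdpn (podoplanin) at −1.44, Sox2 at −0.27 and Trp63, the master regulator of stratified epithelium, at −0.18 (edgeR adjusted p from 0.455 to 0.793). Kallikreins and serine protease inhibitors were higher, with 16 of 20 members higher and a mean of 0.29 (camera adjusted p = 4.69e-05; adjusted p = 0.99 with an estimated correlation). The mean was 0.18 without Grhl3 KO library 1043, 0.17 without wild-type library 1048 and 0.19 without wild-type library 1561. Again 0 members passed by either adjustment; the matriptase gene St14 was at 0.55, Tmprss11e at 0.97, Serpinb2 at 0.78 and Klk7 at 1.36 (edgeR adjusted p from 0.428 to 0.621).

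The epidermal lipid barrier list missed the threshold (camera adjusted p = 0.0527), with 15 members higher and 8 lower, a mean of −0.26 and a median of 0.05. It passed without Grhl3 KO library 1027, 1036 or 1043 or wild-type library 1048 or 1561, and its mean ran from −0.40 without wild-type library 1048 to −0.14 without wild-type library 1555. Adjusted over the list alone 4 of its 23 members fell, and over all genes 0 did: the sphingomyelinase gene Smpd1 was at −1.48 (26.6 ± 3.76 against 73.9 ± 26.2 CPM), Sdr9c7 at −1.63, and the lipase genes Lipk and Lipm at −1.45 and −1.42 (edgeR adjusted p over all genes 0.0834, 0.243, 0.283 and 0.421). Wound and stress keratinocyte genes had 7 higher and 11 lower (camera adjusted p = 0.885), and Ereg, encoding an EGF receptor ligand, rose when adjusted over the list alone (0.88, edgeR adjusted p = 0.0834 over all genes), beside Defb4 at −1.28. Junction genes had 16 higher and 13 lower (0.0848), with Cldn1 at 0.97 and Dsc3 at 0.29. Planar cell polarity genes had 11 higher and 6 lower (0.885; mean −0.02, median 0.03, test upward), and the 3 grainyhead-like genes gave 0.676. The last 3 lists had no member past either adjustment.

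Among processes, the targets of NRF2, the transcription factor of the oxidative stress response, were higher as a group in camera with a preset correlation. Of 26 members 21 were higher, with a mean log2 fold change of 0.32 (camera adjusted p = 4.69e-05; adjusted p = 0.99 with an estimated correlation). Without Grhl3 KO library 1043 the mean was 0.12. No member passed by either adjustment: the quinone reductase gene Nqo1 was at 308 ± 142 CPM in Grhl3 KO and 156 ± 51.7 CPM in wild type, a log2 fold change of 0.98, and Gclc, Txnrd1 and Srxn1 were at 0.95, 0.48 and 0.55 (edgeR adjusted p from 0.455 to 0.651); without Grhl3 KO library 1043 Gclc was at 0.55 and Srxn1 at 0.33. The p53 targets had 15 higher and 7 lower (camera adjusted p = 0.0527). Their mean log2 CPM was 5.45 ± 0.0906 in Grhl3 KO and 5.28 ± 0.059 in wild type, higher in every Grhl3 KO library than in every wild-type library (exact two-sided permutation p = 0.00794, the smallest possible; adjusted over 41 lists, 0.325). Eda2r, an X-linked receptor gene, rose when adjusted over the list alone (1.14, edgeR adjusted p = 0.166 over all genes), beside Gdf15 at 1.48 and Mdm2 at 0.21, which did not. Gdf15 stood at 3.22 CPM in Grhl3 KO library 1043 and at 0.881 to 1.12 CPM in the other Grhl3 KO libraries. With 1 library left out, its log2 fold change fell to as low as 0.98.

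The other process lists missed the threshold in camera. Interferon response genes had 21 higher and 10 lower (camera adjusted p = 0.0684), of which Oasl1 rose when adjusted over the list alone (2.27, edgeR adjusted p = 0.146 over all genes). The list passed without Grhl3 KO library 1026, 1036 or 1043 or wild-type library 1028 or 1048, and its mean ran from −0.07 without Grhl3 KO library 1035 to 0.92 without wild-type library 1028. Xenobiotic metabolism had 8 higher and 10 lower (0.885), and Aldh1a7 fell when adjusted over the list alone (−2.36, edgeR adjusted p = 0.206 over all genes). No member passed by either adjustment in hypoxia and glycolysis (5 higher, 17 lower, 0.113), epithelial-mesenchymal transition (7 and 15, 0.349), matrix proteases (8 and 11, 0.828), PI3K and AKT (11 and 10, 0.869, mean −0.05 and median 0.01), Notch (7 and 6, 0.885, mean −0.05 and median 0.03), inflammatory cytokines (10 and 17, 0.885), MYC targets (10 and 17, 0.885), cell cycle (19 and 22, 0.885, mean −0.01 and median −0.03 with the test upward) or MHC class II (5 and 5, 0.925, mean −0.07 with the test upward). Of single members, the mitotic gene Cdc20 was at 0.21 and the cytokine gene Tslp at 2.37 (edgeR adjusted p = 0.938 and 0.548). With 1 library left out, Cdc20 ran from 0.04 (without Grhl3 KO 1043) to 0.39 (without wild type 1561) and Tslp reached 3.57 (without wild type 1561). Among RNA quality classes, ribosomal protein genes had 16 higher and 30 lower (0.187), with Rpl37 lower when adjusted over the list alone (−0.78). Immediate early genes had 15 and 10 (0.427), with Jund higher when adjusted over the list alone (0.53), and mitochondrially encoded genes had 9 and 2 (0.676) with no member called. Mitochondrially encoded genes took 2.10 ± 0.0818% of counts in Grhl3 KO and 1.93 ± 0.108% in wild type (SD, n = 5 each; exact two-sided permutation p = 0.0476).

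**Figure D4:**
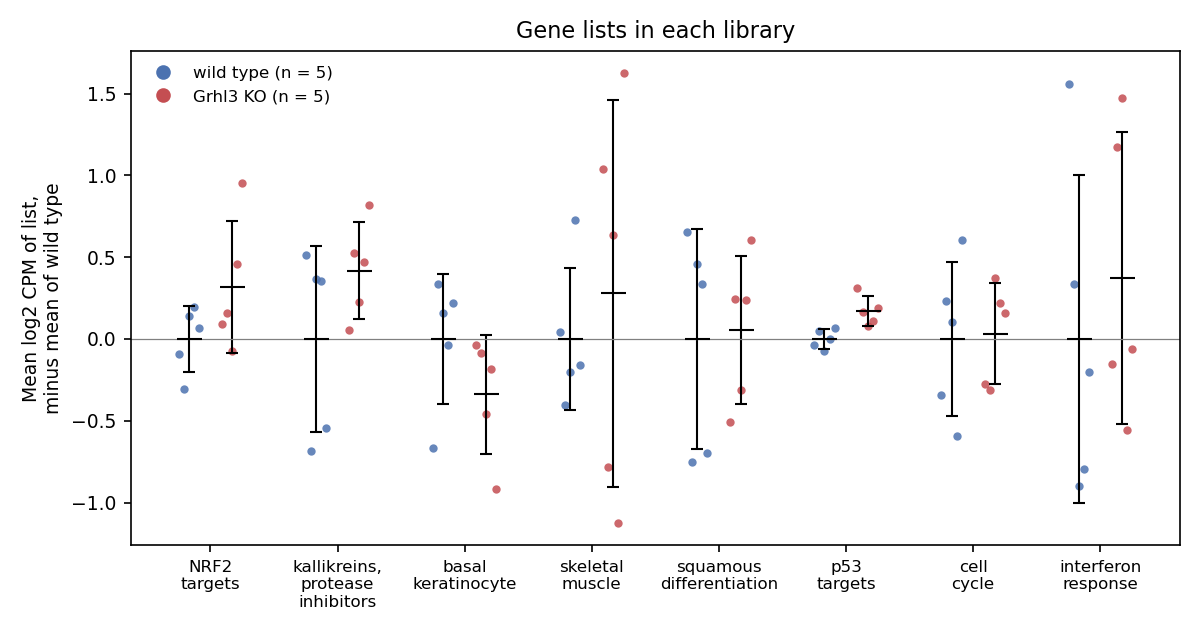
Mean log2 CPM of 8 gene lists in each library, minus the wild-type mean, with the mean ± SD of 5 wild-type (blue) and 5 Grhl3 KO (red) libraries. The p53 targets are the 1 list drawn whose groups do not overlap (5.45 against 5.28 log2 CPM), and the skeletal muscle list spreads widest among Grhl3 KO libraries (SD 1.18).

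Of the markers of other cell types, 1 list passed in camera with a preset correlation, that of skeletal muscle, the tissue of the outer oesophageal wall in mice. All 34 measured members had a higher fitted level in Grhl3 KO, with a mean of 0.56 (camera adjusted p = 0.0152; adjusted p = 0.99 with an estimated correlation), and 0 passed by either adjustment. Acta1 was at 1034 ± 781 against 669 ± 214 CPM, and Actn2 and Myl1 were at 1.19 and 1.02; without Grhl3 KO library 1043 Acta1 was at 0.12 on the log2 scale and Myl1 at 0.63. The list took 0.533 ± 0.330% of counts in Grhl3 KO and 0.395 ± 0.0942% in wild type (exact two-sided permutation p = 0.389, n = 5 each). The call rested on Grhl3 KO library 1043, at 0.991% of counts: without it the mean was 0.13 and the direction of the test turned. The call also ended without Grhl3 KO library 1026 or 1035 or wild-type library 1048, 1528 or 1561, with adjusted p from 8.37e-11 to 0.99 over all alternatives.

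No other cell type list passed in camera. Nerve and Schwann cell genes had 1 higher and 7 lower and respiratory, salivary and thyroid epithelium 3 higher and 0 lower (camera adjusted p = 0.0527 for each), of which Tppp3 rose when adjusted over the list alone (0.76). The exact two-sided permutation p of their mean levels was 0.0397 and 0.0159 (adjusted over 41 lists, 0.542 and 0.325). With 1 library left out, the nerve list passed in 8 of 10 cases, all but wild type 1028 and 1555, with means from −0.74 to −0.40. The respiratory list passed without Grhl3 KO 1026 or wild type 1028, 1048, 1528 or 1555, with means from −0.01 (without Grhl3 KO 1036) to 1.05 (without wild type 1528). Endothelial genes had 14 higher and 5 lower (0.0684), keratinizing skin and hair 0 and 7 (0.0898), mast cells and eosinophils 6 and 2 (0.324), macrophages and monocytes 14 and 6 (0.560), gastric epithelium 0 and 5 (0.603), erythroid genes 0 and 5 (0.869), fibroblasts 13 and 9 (0.885), B and plasma cells 1 and 2 (0.885). The test and the mean differed in sign for T and NK cells (7 and 11, 0.813, mean −0.11 and test upward), adipocytes (5 and 3, 0.813, mean −0.11 and test upward), dendritic and Langerhans cells (3 and 7, 0.885, mean −0.15 and test upward), smooth muscle and pericytes (7 and 9, 0.901, mean −0.10 and test upward) and neutrophils (5 and 7, 0.917, mean 0.02 and test downward). Of the most abundant markers, the macrophage list's Arg1 was at 1026 ± 365 against 920.1 ± 460 CPM and the neutrophil list's S100a8 at 4001 ± 709 against 4818 ± 4058 CPM (edgeR adjusted p = 0.972 and 0.960). S100a8 is also a member of the wound and stress keratinocyte list, and Arg1 stood far above Cd68 of the macrophage list (mean 21.4 CPM). Their levels therefore cannot be read as immune content alone. Except for Tppp3, no member of these cell type lists passed by either adjustment.

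In all, 4 of 41 lists passed in camera with a preset correlation and 0 with an estimated correlation or in fry (smallest adjusted p 0.593 and 0.0656). Every one of 100 ways of dividing the 10 libraries gave at least as many list calls, so the 4 list calls do not set the real groups apart from other divisions of these mice.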

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

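The tests of the Grhl3 to Grhl1 ratio, of missing Grhl3 transcripts and of the number of genes with a p under 0.001 near Grhl3 were chosen after the values were seen. Dividing the 10 libraries in other ways tests whether the calls could come from any grouping. Among 100 of the 126 possible divisions, only the real one gave 11 or more called genes (1 of 100), and the highest other count was 4. For genes higher in Grhl3 KO the count was 2 of 100 (4 genes, highest other 4) and for genes lower 1 of 100 (7 genes, highest other 4). Other divisions thus seldom gave as many gene calls, which decides nothing for a single gene. The divisions also ignore the number series, of which the second lies wholly in the wild-type group. With that series as a batch term, Hmgn2 alone passed. For the 4 list calls, all 100 divisions gave as many, up to 23 lists with a median of 14. This points to a structure of the samples in which the members of a list vary together. The correlation estimated for the 4 called lists was 0.382 to 0.78, against the preset 0.01.

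Several of the smallest p-values lay near Grhl3, among them Hmgn2, Stpg1 and Stmn1. The 5 genes with a p under 0.001 within 5 Mb exceeded every one of 12857 equal windows elsewhere (percentile 100), where the highest number was 2. That count cannot test an even spread of the smallest p-values, because it includes the 4 genes whose small p-values drew attention to the window. A wider test without these 4 genes was negative by its rule: the share with a p under 0.05 was 11.2%, at percentile 89.2 of such windows. The other windows kept their own smallest p-values, so this test leans toward a negative result. It cannot exclude an excess of small p-values near Grhl3. A sex difference is argued against, because 101.9% of the median absolute log2 fold change stayed without the 2 wild-type libraries lacking Y-linked counts. For Hmgn2, reads shared with near-identical copies are a candidate explanation: 92.3% of its transcript has such copies, although shared sequence alone would need a difference between the groups to act on. DNA of another mouse strain carried along with the targeted allele cannot be told apart from an effect of Grhl3 loss. A stretch confined to the neighbourhood should stand alone on chromosome 4. There 1 other window of 10 Mb reached as high a share (14.3% against 19 of 138 genes), but with 3 of 21 genes it is too small to decide. The adjoining windows held 12 of 106 genes (11.3%) at lower positions and 6 of 82 (7.32%) at higher positions. A stretch longer than the window was not tested. No other window there held more than 1 gene with a p under 0.001.

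Grhl3 counts were not lower in the libraries labelled Grhl3 KO. Loss of most of the transcript is argued against, since the lower 95% limit of the log2 fold change was −0.66. With epithelial content as a covariate the log2 fold change was 0.27 (limits −0.22 to 0.76), so it was not lower at equal content either. That covariate pools squamous differentiation genes, Grhl1 among them, with basal keratinocyte genes and does not isolate differentiation state. Whether differentiation state hides a lower level is therefore not decided. Relative to its paralog Grhl1, Grhl3 was lower in Grhl3 KO, by −0.41 on the log2 scale (exact two-sided permutation p = 0.0317, n = 5 each). Grhl1 averaged 214 CPM in Grhl3 KO and 141 CPM in wild type, and Grhl3 222 and 207 CPM. The ratio thus moved with a higher Grhl1 level and does not by itself show a loss of Grhl3. A modest loss was not tested apart from it. A deleted exon in a stable transcript, cells in which the gene was not deleted and wrong labels stay open, since counts per whole gene do not address them.

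Wild-type library 1561 held Y-linked counts at 39.5% of the mean of the 7 other libraries with such counts (33.1 to 52.6% per gene). A mixture with RNA from female tissue would raise X-linked genes that escape inactivation, by 0.26 on the log2 scale under a simple mixing model. The observed shift was 0.0387, within the SD of 0.0932 among those 7 libraries and below the highest of them at 0.14. One library against an assumed profile decides nothing, so a mixture and loss of the Y chromosome in part of the cells cannot be told apart; no biological explanation was tested.

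A single library stood far from the other 4 of its group in 13 of 226 sets of values examined, where chance gives about 11 (5% of groups). In log2 CPM, C130079G13Rik was at −1.30 in Grhl3 KO 1036 (nearest other −0.11), Edn1 at 3.46 in Grhl3 KO 1035 (4.15), Actn2 at 3.79 in wild type 1048 (4.56), Sbsn at 8.28 in wild type 1048 (9.59), Gdf15 at 1.73 in Grhl3 KO 1043 (0.28), Dsc3 at 9.74 in Grhl3 KO 1026 (10.03), Cxcl3 at 0.91 in wild type 1028 (5.44) and Lor at 9.26 in Grhl3 KO 1043 (8.03). Mean log2 CPM of the planar cell polarity list was 5.12 in wild type 1028 (5.35) and 5.54 in Grhl3 KO 1026 (5.30). In Grhl3 KO 1043 it was 5.02 for xenobiotic metabolism (4.44) and 2.998 for erythroid genes (2.26). Skeletal muscle genes took 0.560% of counts in wild type 1555 (0.380%).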

How the results depend on the processing

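The alternatives that leave out 2 or 3 wild-type libraries were chosen after the data were seen. Hmgn2 passed in all 30 alternatives, with log2 fold changes from −3.33 to −2.89. All 11 called genes kept their call and direction under each of the 3 other scalings, where the median log2 fold change of all genes moved by less than 0.1. Grhl3 passed in none and ran from −0.10 to 0.41, so its sign is open. Of 1974 comparisons of named genes under an alternative, 1771 kept their side of the threshold, 174 lost the call, 29 gained it and 0 turned direction with a call before or after; of 1309 for lists these were 1179, 23, 85 and 22. No paired analysis was possible because the groups share no sample numbers.

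DESeq2 called 118 genes, all 11 among them (57 higher, 61 lower; 291 adjusted p-values were not given), limma voom 1 (0 higher, 1 lower) and voom with quality weights 1 (0, 1). Without a filter on low counts 7 passed (4 lower) with 9 lists. Immune content as a covariate gave 6 (2, 4), epithelial content 30 (17, 13) and a surrogate variable 2 (0, 2) with 7 lists. The number series as a batch term gave 1 (0, 1) with 9 lists, its first series alone 1 (0, 1) with 10 lists, and the Y-linked covariate 1 (0, 1) with 9 lists. Without wild type 1528 and 1555 it was 1 (0, 1) with 10 lists. Without 1528, 1555 and 1561 together it was again 1 (0, 1) with 10 lists, and without 1028 and 1528 it was 5 (1 lower) with 12 lists. Of these 5 genes, 1 was among the 11 called with all libraries. The estimated correlation and fry called 0 lists each. Some of these alternatives use fewer samples, while voom, the covariates and the surrogate variable kept all 10 libraries. The batch term kept them too, but the second series holds only wild-type libraries. The group difference under that term therefore rests on the libraries of the first series. The cause of the losses was not tested.

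Leaving out 1 library gave 1 to 16 genes (0 to 11 higher, 1 to 9 lower) and 5 to 11 lists. A single gene, Hmgn2, passed without Grhl3 KO 1027, 1036 or 1043 or wild type 1528. Without wild type 1555, 2 genes passed, 1 of them among the 11 called with all libraries. Without Grhl3 KO 1035, 3 passed, all among the 11. Without wild type 1561, 7 passed, 4 of them among the 11. Lists that missed the threshold with all libraries passed in some of these 10 cases, among them p53 targets in 5, keratinizing skin and hair in 4, junction and endothelial genes in 3 each and hypoxia and glycolysis in 2.

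Lists whose test turned direction with a call before or after had these mean log2 fold changes; the cause was not tested. The means of further lists, and the fold changes of named genes near 0 such as Tgm5 and Arg1, also changed sign under some alternatives. In the first number series alone, which equals leaving out 1528, 1555 and 1561, interferon response was at −0.43, MHC class II −0.54, smooth muscle −0.49, fibroblast −0.22 and T and NK cell −0.76; with the batch term they were −0.43, −0.54, −0.49, −0.22 and −0.63. With the Y-linked covariate cell cycle was at −0.17 and interferon response −0.21, and without 1528 and 1555 cell cycle was at −0.17. Skeletal muscle was at −0.0204 with its own covariate and 0.13 without Grhl3 KO 1043 (0.13 to 0.79 with 1 library left out), squamous differentiation at −0.24 without wild type 1048 (−0.25 to 0.10), and keratinizing skin and hair at 0.56 without 1028 and 1528. At 15.3 to 32.9 M counts per library, genes with too few counts for the filter carry no result in the report; without the filter 18079 genes were tested.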

Other observations

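At an adjusted p between 0.05 and 0.10 in edgeR's quasi-likelihood test there were 7 further genes, 4 higher and 3 lower in Grhl3 KO, for a total of 18 under 0.10. Besides Rhpn2, Stpg1 and Stmn1, these included Hs3st1, encoding a heparan sulfate sulfotransferase (30.5 ± 5.75 against 15.3 ± 3.22 CPM, SD, n = 5 each; edgeR adjusted p = 0.0834), Ereg (77.2 ± 15.5 against 42.0 ± 5.40 CPM) and the sphingomyelinase gene Smpd1 (26.6 ± 3.76 against 73.9 ± 26.2 CPM). Each of these named genes separated the groups in all 10 libraries. Hs3st1 was named after its values were seen.

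At an unadjusted p under 0.05 there were 983 genes, where chance gives about 687 on average. Genes that vary together make such a count vary widely around that number. It was not counted in other divisions of the libraries, so the excess decides nothing.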
